A study of Homo sapiens with 97 samples.

How the data were processed

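Per the labels, nuclei were isolated from postmortem human ventral midbrain, and about 50000 per sort were collected by fluorescence-activated nuclei sorting on NeuN and Nurr1. Libraries were prepared from total nuclear RNA with the SMARTer Stranded Total RNA-Seq Pico v2 kit and sequenced as 100 bp paired reads on a NovaSeq. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.3a, limma and the genome GRCh38/hg38. The authors deposited a table of counts for 58929 genes and a table of TPM for 208621 transcripts, each with 97 library columns, all of which were used. The deposited count values are whole numbers, and the TPM values of each library sum to a fixed total. The program that counted reads, its strand setting, its annotation version and the program that computed TPM were not given in the sources used here.

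Gene identifiers were paired with symbols through the deposited TPM table for 58870 genes. Positions and gene types came from GENCODE 29 for 58656 genes, and 273 identifiers were not found there. Y-linked genes, XIST, TSIX and genes without a known chromosome were left out before any test, 818 in all, which removed a median of 0.196% and at most 0.594% of a library's counts. Of these, 262 had no known chromosome. Genes that overlap on opposite strands cannot be separated with certainty when the strand setting is unknown, and copies of a gene family share reads, so histone, protocadherin and small nucleolar RNA genes are reported mainly as groups. No 2 libraries held the same counts, and the highest correlation between libraries was 0.990.

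Groups followed the sort and diagnosis in the labels. Each library carried its own donor number, so libraries were treated as independent and no pairing of the 2 sorts was attempted. Information on single donors was not used as a covariate. Comparisons, tests, gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Alternatives added later are named as such in the closing section.

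Gene tests used edgeR 4.0.16 in R 4.3.3 with TMM normalization, filterByExpr and the quasi-likelihood F test, two-sided. SCZ, BP and Control were compared within each sort in 1 fit of the 3 groups, over 23779 genes in the Dopa neuron and 24755 in the Non neuron sorts. The 2 sorts were compared in Control libraries over 20976 genes, and interactions were contrasts in 1 fit of 6 groups over 27328 genes. The Benjamini-Hochberg method adjusted p over all tested genes, and a gene was called at an adjusted p under 0.05. Fold changes of genes used the default prior count of edgeR, and the log2 CPM values behind the list and bin tests a prior count of 2. Named genes were the 12 called genes with the lowest p in each direction among those with an average log2 CPM of at least 1, leaving out clone names, noncoding RNA families, antisense names and pseudogenes. Where fewer than 10 were called, the 5 genes with the lowest p that were not called are given. Adjusted p values of genes are those of edgeR unless another tool is named.

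Gene groups were 12 cell type marker lists (dopamine neuron, GABAergic neuron, glutamatergic neuron, serotonin neuron, pan-neuronal, oligodendrocyte, oligodendrocyte precursor, astrocyte, microglia, endothelial and mural, T lymphocyte, ependymal) and 20 lists of processes. The 20 were dopamine synthesis and handling, oxidative phosphorylation, mitochondrially encoded proteins, ribosomal proteins, heat shock, immediate early, glucocorticoid response, synaptic vesicle, voltage-gated channels, glutamate receptors, GABA receptors, schizophrenia rare and common variant genes, bipolar common variant loci, inflammation, cholesterol synthesis, cohesin and genome folding, proteasome, clustered protocadherins and replication-dependent histones. Both sets were written from general knowledge of the field, and TH, DDC, SLC6A3, SLC18A2 and DRD2 are in both dopamine lists. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the libraries, and with fry. Adjustment ran over the lists of a comparison. camera sets a list against the other genes, and fry tests whether a list moves on balance in one direction.

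A marker index was the mean log2(CPM + 1) of a list in a library, with 0.1 in place of 1 as an alternative. Group differences were tested by two-sided exact enumeration or by 100000 permutations, adjusted over 12 lists. Correlations across libraries carry permutation p values. Chromosomal domains were 1 Mb bins of autosomes with at least 5 tested genes, tested with camera. The correlation between adjacent genes was set against 1000 shuffles of gene order.

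Alternatives were RLE size factors, no filter on low counts, limma-voom, DESeq2 1.42.0, 2 surrogate variables from sva 3.50.0, a glial or pan-neuronal index as a covariate, only the 2 groups compared, libraries under 0.5 of the median total of their sort left out (4), bins of 0.5 and 2 Mb, an estimated correlation and fry. Added later were the dopamine neuron index or log2 total count as covariates, the Dopa neuron SCZ library richest in microglial markers left out, libraries carrying over 10% of the other sort's Control median of markers left out, and the TPM table summed per gene with limma on log2(TPM + 0.5). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.

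The gene and list tests were tested on simulated data of the same size and dispersion, with 200 changed genes. These were drawn from genes with an average log2 CPM of at least 1, so recovery below that level was not measured. For SCZ against Control in the Dopa neuron sorts 12% of 1.5-fold, 62% of 2-fold, 94% of 4-fold and 98% of 8-fold changes were recovered, with 5 false among 138 calls. For BP against Control there these were 20%, 50%, 88% and 100%, and for SCZ against BP 8%, 38%, 82% and 100%. In the Non neuron sorts they were 38%, 72%, 100% and 100% for SCZ and 12%, 54%, 96% and 100% for BP, and between sorts 48%, 74%, 96% and 100%. False calls numbered 5 to 10 in each. Planted lists were recovered in each comparison, and 1 other list was called. Simulated genes varied independently of one another, so these figures do not cover genes that vary together across libraries. Other divisions of the real Dopa neuron libraries called a median of 8 lists for SCZ and for BP against Control.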

Results

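Nuclei from human postmortem ventral midbrain were sorted into 2 fractions, and the RNA of each sorted fraction was sequenced as 1 library. The Dopa neuron fraction holds nuclei gated on the neuronal protein NeuN and the dopamine neuron transcription factor Nurr1. The other fraction is labelled Non neuron, and oligodendrocyte, astrocyte and microglial markers were high and pan-neuronal markers low in it. Donors had schizophrenia (SCZ), bipolar disorder (BP) or neither (Control). The Dopa neuron sorts comprised 24 Control, 8 SCZ and 9 BP libraries. The Non neuron sorts comprised 26 Control, 22 SCZ and 8 BP libraries, so that 97 libraries were compared in 6 groups.

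Total counts per library ran from 2723880 to 71688400, with a median of 11732000. In the Dopa neuron sorts the range was 6174250 to 71688400 for Control, 7672360 to 13498500 for SCZ and 5173530 to 39818700 for BP. In the Non neuron sorts it was 7281190 to 30719300 for Control, 3512670 to 22813400 for SCZ and 2723880 to 28911100 for BP. A median library detected 32265 genes and placed 83.6% of its counts on protein-coding genes. Mitochondrially encoded RNA took a median of 0.311% of the counts. Abundances below are mean CPM (counts scaled to library size) ± SD, and changes are log2 fold changes with their SE. Positions refer to GRCh38 with GENCODE 29. Throughout, a library is said to be on the side of a change when its CPM lies beyond the median of the reference group.

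Comparing the 2 sorts of the Control donors asks which transcripts the nuclear gate separated. Neuronal synaptic and channel genes were far more abundant in the Dopa neuron sorts. GRIN1, the obligatory NMDA receptor subunit, stood at 1103 ± 530 against 14.6 ± 12.6 CPM. The calcium channel gene CACNA1C stood at 411 ± 116 against 39.6 ± 17.4 CPM. Oligodendrocyte genes showed the opposite distribution, with MOG at 33.2 ± 41.3 in the Dopa neuron sorts and 899 ± 255 CPM in the Non neuron sorts. Of 20976 genes tested with edgeR, 7567 were higher and 7611 lower in the Dopa neuron sorts.

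Among the genes separated most clearly, each on the same side in 24 of 24 Dopa neuron libraries, the kinase gene MAP3K9 (ENSG00000006432.15, chromosome 14, 70722526 to 70809534) was higher by 4.18 ± 0.138, adjusted p 9.87e-31. Its abundance was 158 ± 25.1 against 8.54 ± 3.42 CPM. PAK3, a kinase of dendritic spines, was higher by 4.27 ± 0.15, adjusted p 5.54e-30. The RNA-binding protein gene CELF4 (chromosome 18, 37243047 to 37566037) was higher by 5.11 ± 0.192. SCN8A, which encodes a sodium channel of the axon initial segment, rose by 3.18, and the NMDA receptor gene GRIN2B (chromosome 12, 13437942 to 13981957) by 4.04. GABBR2, EPHB1, ARHGAP44, PHF24 and NCR3LG1 rose by 4.63, 2.97, 3.45, 4.87 and 3.61. The noncoding host gene SNHG14 on chromosome 15, which is paternally expressed in neurons, was among the most abundant at 5217 ± 989 against 907 ± 161 CPM.

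In the other direction TMC7 (chromosome 16, 18983934 to 19063942) was lower by -3.35 ± 0.115, adjusted p 2.47e-30, with 11.8 ± 3.08 against 118 ± 31.9 CPM. The phosphatase gene PHLPP1 was lower by -3.55 and the actin nucleator COBL (chromosome 7, 51016212 to 51316818) by -3.83. PXK, USP54, PDE8A and ELMO1 changed by -3.59, -3.12, -3.01 and -2.58. Smaller differences were those of OSBPL1A at -2.48, KAT2B at -2.33, C12orf76 at -2.15 and ARHGAP17 at -1.43.

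Marker lists located the neuronal types that the gate had collected. Of 12 dopamine neuron markers tested, 11 were higher, at a median of 3.00, among them LMX1B at 4.22, KCNJ6 at 3.63, RET at 3.53 and DRD2 at 3.35. GABAergic markers were separated at least as strongly, with 6 of 7 higher at a median of 4.34. GAD2 stood at 150 ± 90.9 against 3.99 ± 3.71 CPM, a change of 5.18, and GATA3 and SLC32A1 rose by 5.01 and 4.34. All 3 glutamatergic markers were higher at a median of 3.48, and SLC17A6 rose by 3.84 from a level of 1.54 ± 3.43 CPM. All 10 pan-neuronal markers were higher, at a median of 3.44, with SYT1 at 4.47 and SNAP25 at 3.33. NR4A2, which encodes the sorted antigen Nurr1, differed less, by 0.96 ± 0.333, adjusted p 0.00858. RBFOX3, which encodes NeuN, rose by 6.22 ± 0.386. The 4 ependymal markers tested were also higher in the neuronal sorts, at a median of 2.92, with DNAAF1 at 5.11.

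Glial markers were lower in the Dopa neuron sorts without exception in 4 lists. The medians were -4.42 over 10 oligodendrocyte genes, -3.57 over 6 precursor genes, -3.57 over 9 astrocyte genes and -3.46 over 10 microglial genes. OPALIN, PDGFRA, ALDH1L1 and CSF1R fell by 5.39, 4.04, 3.83 and 3.65. GFAP stood at 40.1 ± 43.9 against 565 ± 501 CPM. Endothelial and mural genes were separated little, with 2 of 8 lower and a median of -0.50, or 1 lower when adjusted over the list alone. Fewer than 3 serotonin and T lymphocyte markers passed the count filter, so these 2 lists were not counted here.

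**Figure D1:**
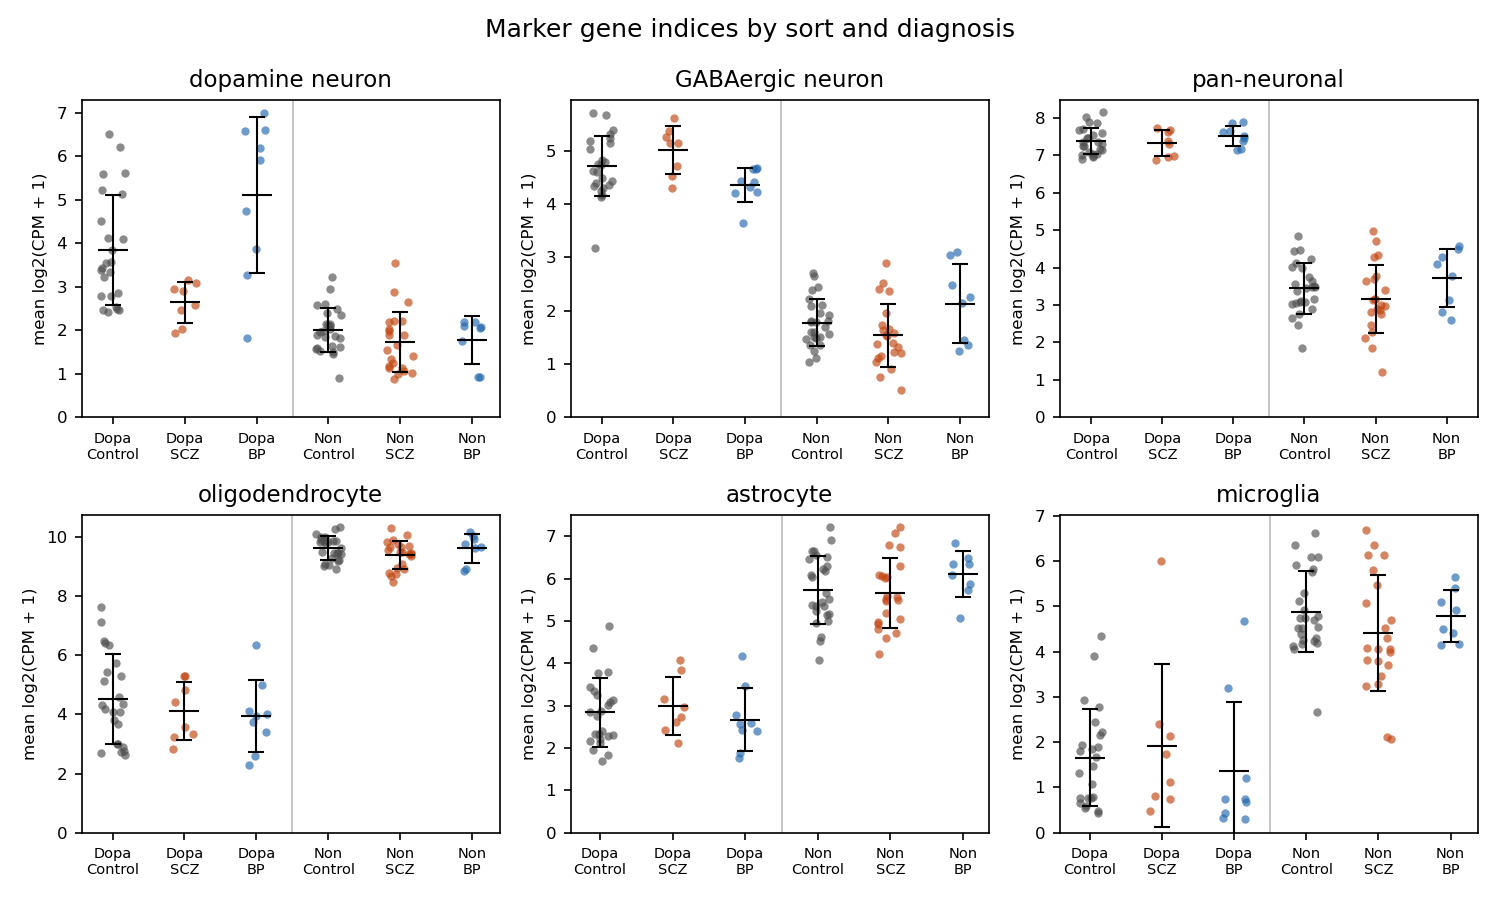
Mean log2(CPM + 1) of 6 marker lists in each library (points) of the 6 groups, with the group mean and SD as bars. The dopamine neuron index was 3.84 ± 1.27 in Dopa neuron Control, 2.64 ± 0.465 in SCZ and 5.11 ± 1.79 in BP libraries.

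Functional lists divided along the same line. All 19 synaptic vesicle genes, all 13 GABA receptor genes, 23 of 25 voltage-gated channel genes and 18 of 22 glutamate receptor genes were higher in the neuronal sorts, at medians of 2.74, 4.30, 2.60 and 2.34. In these lists 1 channel gene and 2 glutamate receptor genes were lower. Dopamine synthesis and handling genes split, with 7 of 11 higher, DDC at 3.14 and GCH1 at 2.48, and 3 lower, including the pterin reductase gene QDPR at -3.10. Nuclear-encoded oxidative phosphorylation genes were higher for 25 of 41 at a median of 0.43, whereas 0 of 13 mitochondrially encoded genes passed in edgeR, at a median of -0.45. Among 50 cytosolic ribosomal protein genes 32 were lower and 1 higher, at a median of -0.43. Proteasome genes were higher for 8 and lower for 3 of 25, at a median of 0.09, and 7 and 3 when adjusted over the list alone.

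Stress and immune genes favoured the Non neuron sorts. All 9 glucocorticoid response genes were lower in the neuronal sorts at a median of -2.38, with FKBP5 at -3.41 and SGK1 at -2.66. The heat shock list had 7 of 12 lower at a median of -0.95, with HSPA1A at -3.11. Immediate early genes split, since FOS and JUN changed by -1.80 and -1.96 while the neuronal factor NPAS4 rose by 4.69, giving 2 higher and 5 lower of 12 at a median of -0.69. Inflammation genes were lower for 15 of 17 at a median of -2.06, with complement C3 at -4.35. Cholesterol synthesis genes were higher for 5 and lower for 5 of 12 at a median of 0.25. Replication-dependent histone genes were lower for 25 and higher for 2 of 31, at a median of -1.38, and HIST1H2BC changed by -3.16. The histone genes are near copies of one another, so counts could not be assigned to single members with certainty.

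Genes at psychosis risk loci were counted in the same way, without a test of the lists against other genes. For schizophrenia common variant loci 16 of 30 genes were higher and 10 lower, at a median of 0.76, and for bipolar loci 11 of 14 were higher and 1 lower, at a median of 1.54. TRANK1 stood at 825 ± 296 against 33.8 ± 17.7 CPM, a change of 4.58, CACNA1C rose by 3.34 and SCN2A by 3.22. The 10 genes with rare schizophrenia coding variants divided into 4 higher and 2 lower, at a median of 0.12. Cohesin and genome folding genes were lower for 8 of 11 at a median of -0.58, with CTCF at 35.5 ± 7.56 against 60.1 ± 9.20 CPM and STAG2 at -1.11. Clustered protocadherins were higher for 24 and lower for 5 of 52 at a median of 0.31, or 22 and 3 over the list alone. PCDHAC2 rose by 1.70 and PCDHGC3 fell by 1.54.

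Comparing SCZ with Control in the Dopa neuron sorts asks whether the transcriptome of this sorted fraction differs in schizophrenia. Genes of dopamine identity were low in the SCZ libraries. SLC6A3, the dopamine transporter gene (ENSG00000142319.18, chromosome 5, 1392790 to 1445430), stood at 4.47 ± 2.03 CPM in 8 SCZ libraries against 48.3 ± 72.5 in 24 Control libraries, with medians of 4.63 and 14.8. SLC18A2, the vesicular monoamine transporter gene (chromosome 10, 117241073 to 117279430), stood at 5.20 ± 2.88 against 53.8 ± 81.0 CPM. TH, which encodes the rate-limiting enzyme of dopamine synthesis, stood at 11.3 ± 7.21 against 49.9 ± 53.1 CPM. Each was below the Control median in 8 of 8 SCZ libraries. In edgeR none passed the adjustment over all genes, with adjusted p 0.868 for SLC6A3 (-3.42 ± 0.899), SLC18A2 (-3.36 ± 0.918) and TH (-2.15 ± 0.685). In DESeq2 SLC6A3 and SLC18A2 passed, at adjusted p 0.014 and 0.0172.

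No single gene was called in edgeR among 23779 tested, and 1331 had an unadjusted p under 0.05. limma-voom called 0 and DESeq2 called 6, of which 2 were higher and 4 lower. The lowest p belonged to F13A1, a macrophage transglutaminase gene, at 70.7 ± 187 against 5.33 ± 6.28 CPM, 3.74 ± 0.751, adjusted p 0.135, above the Control median in 4 of 8. Without the SCZ library richest in microglial RNA its change was -0.23 with adjusted p 0.988. PLTP, a phospholipid transfer protein gene, changed by 1.86 ± 0.445, adjusted p 0.551, in 5 of 8. NOMO3, a member of a set of near-identical copies on chromosome 16, changed by -1.39 ± 0.342, adjusted p 0.658, in 8 of 8, and passed in DESeq2 at 0.0412. With no filter on low counts edgeR called 3 of the 5 named genes of lowest p (F13A1, PLTP, NOMO3, SLC6A3 and SLC18A2).

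**Figure D2:**
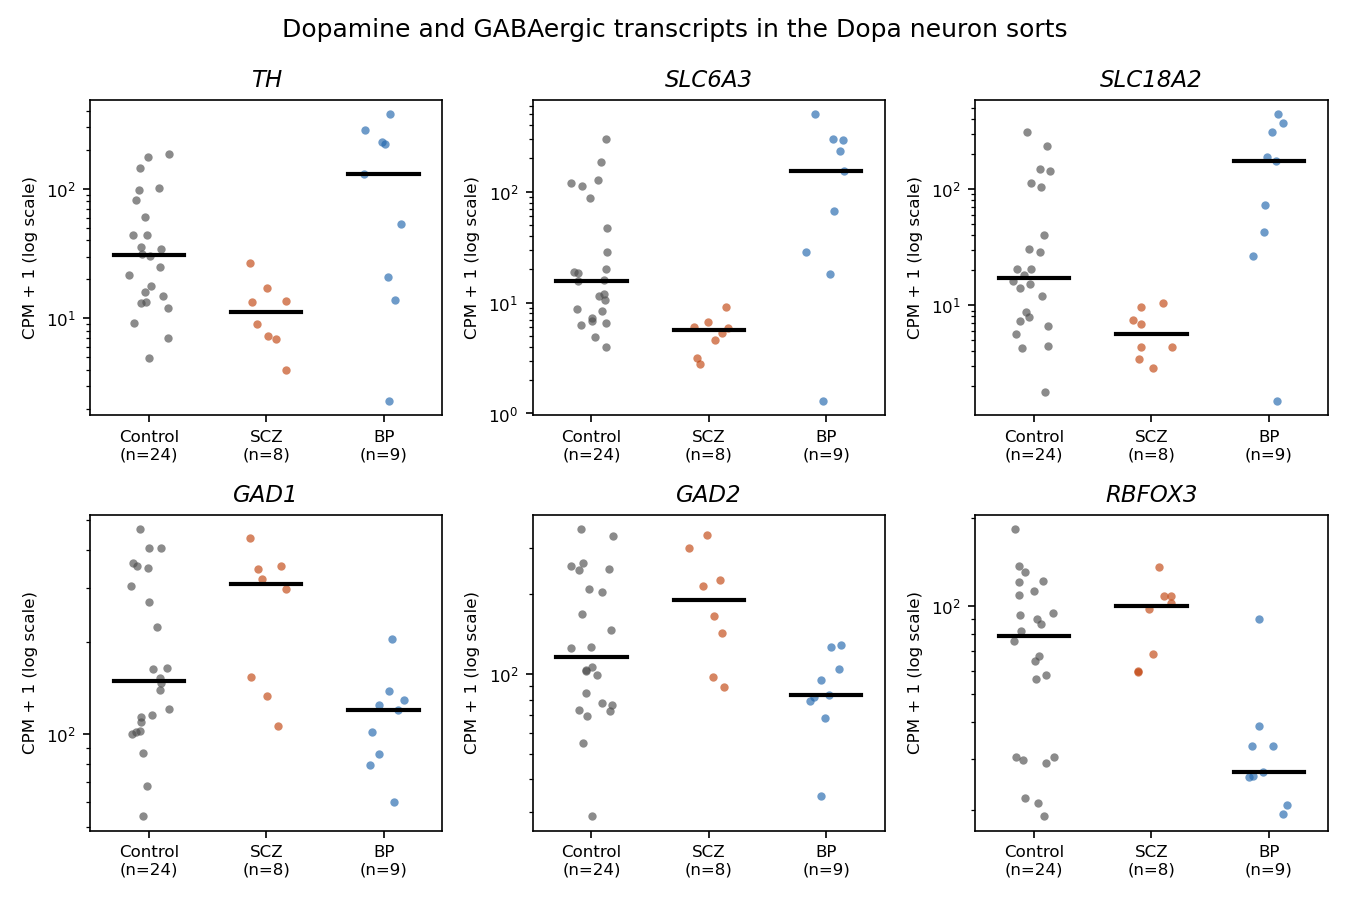
CPM + 1 on a log axis of 3 dopamine and 3 other neuronal transcripts in each Dopa neuron library (points), by diagnosis, with the group median as a line. The median of SLC6A3 was 14.8 CPM in Control, 4.63 in SCZ and 154 in BP libraries.

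As a group, dopamine neuron markers lay below Control in SCZ. Of 14 tested, 0 had a positive change and the median was -2.05 (camera adjusted p 6.25e-13). In edgeR all 14 were lower when adjusted over the list alone and 0 over all genes, while DESeq2 called SLC6A3 and SLC18A2 over all genes. Adjusted p = 0.587 with an estimated correlation. Dopamine synthesis and handling genes followed at a median of -0.41, with 1 of 12 positive, adjusted p 0.00013 and DDC at -2.33. Adjusted p = 0.589 with an estimated correlation, and 5 were lower over the list alone. The dopamine neuron index differed by -1.20 between the groups (exact p 0.0131, 0.157 after Benjamini-Hochberg adjustment over 12 lists, two-sided). It ran from 1.944 to 3.16 in the SCZ and from 2.43 to 6.515 in the Control libraries of the Dopa neuron sorts. All SCZ values thus lay within the range of the Non neuron Control libraries, 0.8918 to 3.219, so these sorts showed little dopamine signal above that of the glial sorts. The GABAergic index was 5.01 ± 0.447 in SCZ and 4.71 ± 0.568 in Control libraries, exact p 0.186, and the pan-neuronal index 7.32 ± 0.350 and 7.38 ± 0.356, exact p 0.658.

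Replication-dependent histone genes moved the other way in SCZ. Of 33 tested, 30 had a positive change at a median of 0.68 (camera adjusted p 7.52e-10), and 10 were higher over the list alone, 0 over all genes. Adjusted p = 0.589 with an estimated correlation. HIST1H2BD stood at 11.3 ± 19.2 against 3.29 ± 2.85 CPM, a change of 1.80 in 7 of 8 libraries, and HIST1H2BF, HIST2H2BF and HIST1H2BC changed by 2.20, 1.88 and 1.82. Inflammation genes had 17 of 18 positive changes at a median of 1.17, adjusted p 0.0108, with CD163, C1QB and C3 at 2.51, 2.38 and 2.36, each in 3 of 8 libraries. Adjusted p = 0.872 with an estimated correlation, and 0.708 with the preset correlation when the SCZ library richest in microglial RNA was left out. Ribosomal protein genes had 41 of 50 positive changes at a median of 0.10, adjusted p 0.00547. Adjusted p = 0.872 with an estimated correlation, and 0.163 with the preset correlation without that library. In these 2 lists 0 genes passed over the list alone. The microglial index was 1.93 ± 1.79 in SCZ and 1.65 ± 1.07 in Control libraries.

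The other 25 lists did not pass. Oligodendrocyte markers had a median of -1.03, adjusted p 0.081, and GABAergic markers a median of 0.42, adjusted p 0.0549. For the 13 mitochondrially encoded genes the median was -0.03 and the mean -0.06 while the test pointed up, adjusted p 0.0586. fry, which tests whether a list moves on balance in one direction, called 0 lists.

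Comparing BP with Control in the Dopa neuron sorts asks the same question for bipolar disorder. Dopamine genes stood high in the BP libraries. SLC6A3 reached 177 ± 170 CPM in 9 BP libraries against 48.3 ± 72.5 in 24 Control libraries, a change of 1.87 in 8 of 9. TH reached 147 ± 136 against 49.9 ± 53.1 CPM, a change of 1.57 in 6 of 9, and SLC18A2 changed by 1.74 in 8 of 9. RBFOX3, which encodes the sorted antigen NeuN, stood at 33.9 ± 21.5 against 76.5 ± 43.7 CPM, a change of -1.17 ± 0.330, adjusted p 0.191. NR2F2 and OTX2, transcription factors of midbrain GABAergic lineages picked outside the naming rule, changed by -1.87 and -2.29, adjusted p 0.192 and 0.198.

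edgeR called 0 of 23779 genes and gave 3690 with an unadjusted p under 0.05. limma-voom called 6 and DESeq2 124, of which 34 were higher and 90 lower. The lowest p values were those of ITPR1, an intracellular calcium release channel gene (chromosome 3, 4493345 to 4847840), at 348 ± 95.3 against 202 ± 72.8 CPM. ITPR1 changed by 0.79 ± 0.171 in 9 of 9 libraries, adjusted p 0.191. At the same adjusted p, the lipase gene ABHD2 changed by 0.84 ± 0.186 in 9 of 9, the iron exporter gene SLC40A1 by 1.26 in 8 of 9 and TXNDC15 by 0.59 in 8 of 9. TFAP2E, a transcription factor gene, stood at 11.2 ± 7.22 against 25.4 ± 11.5 CPM, a change of -1.19 in 8 of 9. DESeq2 called all 5, ITPR1 at adjusted p 0.0242, ABHD2 at 0.0276, SLC40A1 at 0.0303, TXNDC15 at 0.0361 and TFAP2E at 0.0216. limma-voom called TFAP2E and SLC40A1, both at 0.0348.

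All 14 dopamine neuron markers had positive changes in BP at a median of 1.43 (camera adjusted p 5.41e-06). Adjusted p = 0.875 with an estimated correlation, and 11 were higher over the list alone, 0 over all genes. KCNJ6, a potassium channel gene of nigral neurons, reached 709 ± 475 against 301 ± 277 CPM, a change of 1.24 in 8 of 9, and SLC10A4, RET and DRD2 changed by 1.76, 1.42 and 1.40. Dopamine synthesis and handling genes were positive for 11 of 12 at a median of 0.58, adjusted p 0.00324, with 4 higher over the list alone. For this list and the next 3 adjusted p = 0.875 with an estimated correlation. Clustered protocadherins had 9 of 52 positive changes at a median of -0.29, adjusted p 1.01e-05, with PCDHA2 at 1.48 ± 0.498 against 3.10 ± 1.35 CPM, lower in 9 of 9 and the 1 member past adjustment over the list alone. Inflammation genes had a median of -0.59 with 4 of 18 positive, and ribosomal protein genes a median of -0.12, both at adjusted p 0.0424 with 0 past it over the list alone. The dopamine neuron index was higher by 1.27 (exact p 0.03, 0.36 after adjustment over 12 lists). fry called 0 lists.

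Comparing SCZ with BP in the Dopa neuron sorts asks whether the 2 disorders differ from each other. Dopamine genes were far lower in the SCZ libraries. SLC6A3 was lower in SCZ by -5.29 ± 1.04, with 4.47 ± 2.03 CPM in 8 SCZ libraries and 177 ± 170 in 9 BP libraries. SLC18A2 was lower by -5.10 ± 1.06, at 5.20 ± 2.88 against 180 ± 161 CPM, and TH (chromosome 11, 2163929 to 2171877) by -3.72 ± 0.802, at 11.3 ± 7.21 against 147 ± 136 CPM. All 3 were below the BP median in 8 of 8 SCZ libraries at adjusted p 0.0233. edgeR called 887 of 23779 genes, 370 higher and 517 lower in SCZ. limma-voom called 2175, with 1361 higher and 814 lower, and DESeq2 2097, with 991 higher and 1106 lower. These included 808 and 885 of the 887. With no filter on low counts edgeR called 1921 higher and 835 lower, so the balance of directions depended on tool and filter.

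Among other genes lower in SCZ, SLC10A4, a vesicular transporter gene of monoamine and cholinergic neurons (chromosome 4, 48483343 to 48489196), fell by 3.71. ZAR1, which begins at 48490252 on the same strand, fell by 4.57, and transcription running on from SLC10A4 was not excluded for it. GFRA1, the receptor of the dopamine neuron survival factor GDNF, stood at 33.8 ± 4.91 against 203 ± 165 CPM, a change of -2.57 ± 0.538. PEX5L, a regulator of HCN pacemaker channels, stood at 44.3 ± 17.3 against 167 ± 78.4 CPM, a change of -1.90 ± 0.382. DRD2, the autoreceptor gene, fell by 2.93. HHLA1 fell by 4.01 ± 0.769, SDC1 by 3.72, CCN3 by 2.57, CATSPERG by 2.52, KCTD6 by 1.56 and MYOM1 by 1.22. Each of these was lower in 8 of 8 SCZ libraries at adjusted p 0.0233. NR4A2 changed by -2.15 ± 0.637, adjusted p 0.0469. SOX6 and AGTR1 were picked from the called genes, outside the naming rule, as genes of ventral-tier dopamine neurons. SOX6, a transcription factor, changed by -2.52 ± 0.588, adjusted p 0.0245, and the angiotensin receptor gene AGTR1 by -5.27, adjusted p 0.0325.

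Among genes higher in SCZ than BP, the circadian repressor NR1D1 (ENSG00000126368.6, chromosome 17, 40092787 to 40100725) stood at 44.8 ± 22.0 against 8.75 ± 9.66 CPM, a change of 2.37 ± 0.532, adjusted p 0.0234. TFAP2E stood at 31.9 ± 11.7 against 11.2 ± 7.22 CPM, a change of 1.53 ± 0.321. PLEKHG2 changed by 2.62 ± 0.597, adjusted p 0.0242, and FGFR4 by 2.33 ± 0.519. ATP8B3, NTN5, ZNF578 and STARD8 rose by 1.52, 2.10, 1.20 and 2.00, and ADAMTS15 by 1.56, adjusted p 0.0245. RASA4 and POLR2J4 rose by 1.52 and 1.40, and both lie in families of near-identical copies on chromosome 7. Each gene named so far in this paragraph was above the BP median in 8 of 8 SCZ libraries. PLTP rose by 2.79 ± 0.607, adjusted p 0.0233, but by 1.28 with adjusted p 0.11 without the SCZ library richest in microglial RNA. Of the 24 genes named by rule for SCZ against BP, DESeq2 and limma-voom each called 23. SOX14, a factor of midbrain GABAergic neurons, stood at 102 ± 61.7 against 11.9 ± 23.1 CPM, a change of 3.10 ± 0.804, adjusted p 0.0313. GAD1 rose by 1.25 ± 0.374, adjusted p 0.0496, in 7 of 8 libraries. RBFOX3 rose by 1.45, adjusted p 0.0343. OTX2 and NR2F2, picked from the called genes outside the naming rule, rose by 2.97 and 2.45, adjusted p 0.0399 and 0.0371.

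**Figure D3:**
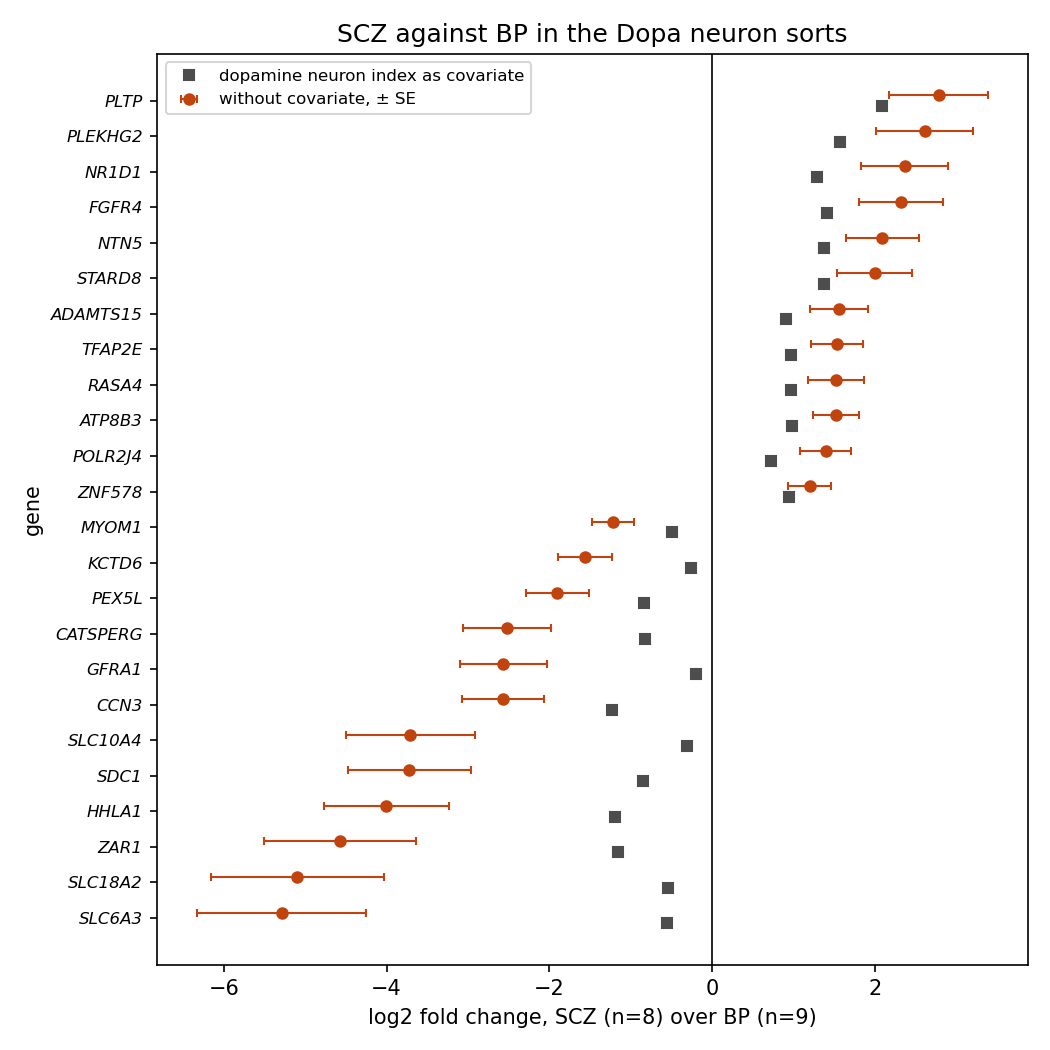
Log2 fold change of SCZ (8 libraries) over BP (9 libraries) in the Dopa neuron sorts for the 24 named genes, without a covariate (circles, bars are SE) and with the dopamine neuron marker index as a covariate (squares). GFRA1 moved from -2.57 to -0.20 and NR1D1 from 2.37 to 1.29, SLC6A3, SLC18A2 and SLC10A4 are members of the index, and all 24 squares had an adjusted p of 1.00.

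Marker indices showed the same opposition. The dopamine neuron index was lower in SCZ than BP by -2.47 (exact p 0.00346, adjusted 0.0237 over 12 lists) and the GABAergic index higher by 0.65, at 5.01 ± 0.447 against 4.36 ± 0.324 (exact p 0.00395, adjusted 0.0237). Of 14 dopamine neuron markers 13 were lower over all genes and 14 over the list alone, at a median of -3.58 (camera adjusted p 1.06e-11, fry adjusted p 0.0165). Adjusted p = 0.701 with an estimated correlation. Dopamine synthesis and handling genes had a median of -0.99 with 5 lower, 7 over the list alone (camera adjusted p 6.24e-05, fry adjusted p 0.0337). Adjusted p = 0.701 with an estimated correlation. GABAergic markers had a median of 1.11 with 3 of 8 higher, or 5 higher and 2 lower over the list alone (camera adjusted p 0.0371, fry adjusted p 0.0672). Adjusted p = 0.872 with an estimated correlation, and 0.0605 with the preset correlation without libraries that carried markers of the other sort.

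Outside the neuronal type markers 6 lists passed camera with the preset correlation, and adjusted p = 0.872 with an estimated correlation for each. Histone genes had 30 of 33 positive changes in SCZ against BP at a median of 1.30, adjusted p 0.000118. HIST1H2BH, HIST1H2BD and HIST1H1C changed by 3.66, 2.35 and 2.15, and 3 members passed over all genes, 14 over the list alone. Protocadherins had 43 of 52 positive changes at a median of 0.40, adjusted p 0.000118, with 1 past adjustment, and PCDHA2 changed by 1.06. Ribosomal protein genes had 43 of 50 positive at a median of 0.19, adjusted p 0.00209, with 2 past adjustment. All 18 inflammation genes were positive at a median of 1.70, adjusted p 0.0027, with IFITM3 at 3.08 past adjustment and 3 over the list alone. Without the SCZ library richest in microglial RNA the inflammation list had adjusted p 0.072. Proteasome genes had 2 of 25 positive at a median of -0.23, adjusted p 0.0109, and mitochondrially encoded genes 11 of 13 at a median of 0.11, adjusted p 0.0371, each with 0 past it over the list alone. None of the 6 passed fry, with adjusted p 0.243 for histones, 0.294 for protocadherins, 0.493 for mitochondrially encoded genes and 0.358 for the other 3. With the dopamine neuron index as a covariate, with 2 surrogate variables or with limma on log2 TPM in place of edgeR on counts, 0 of the 887 genes stayed past adjustment. With the log2 total count as a covariate 154 stayed, and 174 stayed without libraries that carried markers of the other sort.

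Comparing SCZ with Control in the Non neuron sorts asks whether glial nuclei differ in schizophrenia. The glucocorticoid-induced cochaperone gene FKBP5 stood at 227 ± 145 CPM in 22 SCZ libraries against 119 ± 129 in 26 Control libraries, a change of 0.95 in 18 of 22. KLF9, another glucocorticoid target, stood at 76.8 ± 35.3 against 46.5 ± 33.4 CPM, 0.76 in 19 of 22. MT-ND5, a subunit of complex I encoded in mitochondria, stood at 722 ± 624 against 411 ± 453 CPM, 0.85 in 18 of 22. None of these 3 passed adjustment. Mitochondrially encoded transcripts come from outside the nucleus, so their level in sorted nuclei also depends on carry-over. Carry-over was not separated from a change in the cells for these genes in any comparison. edgeR called 0 of 24755 genes and gave 1131 with an unadjusted p under 0.05. limma-voom called 0, and DESeq2 called 11, of which 8 were higher and 3 lower.

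The lowest p values, all at adjusted p 0.302, were those of FMO5, CLTCL1, CACNA2D4, ADHFE1 and TACC1. TACC1, a microtubule-associated gene, stood at 326 ± 53.0 against 263 ± 47.1 CPM, 0.33 ± 0.0806 in 20 of 22. FMO5 changed by 1.13 ± 0.265 in 16 of 22 and CLTCL1, a clathrin heavy chain gene, by 0.69 ± 0.163 in 19 of 22. CACNA2D4 and ADHFE1 changed by 1.30 and 0.62, each in 18 of 22. All 5 were among the 11 genes called by DESeq2, at adjusted p 0.0184 for TACC1, 0.0284 for FMO5, 0.0295 for CACNA2D4, 0.035 for CLTCL1 and 0.0366 for ADHFE1. DESeq2 gave no adjusted p to 9599 of the 24755 genes here, so its adjustment ran over fewer genes than that of edgeR.

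Among the gene lists 12 passed with the preset correlation and 0 with an estimated one. Adjusted p = 0.611 with an estimated correlation for the dopamine neuron, mitochondrial, glucocorticoid and GABA receptor lists, and 0.66 for the others. The 13 mitochondrially encoded genes were all positive in SCZ at a median of 0.75 (camera adjusted p 2.3e-10), with MT-CO3 at 0.80. Nuclear-encoded oxidative phosphorylation genes had 8 of 41 positive at a median of -0.12, adjusted p 0.00209. The glucocorticoid list had 7 of 9 positive at a median of 0.28, adjusted p 0.00209, with 2 higher over the list alone. Histone genes had 42 of 50 positive at a median of 0.55, adjusted p 0.00149, with 8 higher over the list alone, HIST1H2AK at 1.24 and HIST1H1D at 1.44. Cholesterol synthesis genes had 1 of 12 positive at a median of -0.25, adjusted p 0.0141, and SQLE at 29.6 ± 9.82 against 45.9 ± 25.0 CPM was the 1 lower over the list alone. GABA receptor genes had a median of -0.37, adjusted p 0.00147. Lower on balance were also microglial markers at -0.14 (adjusted p 0.000655), dopamine neuron markers at -0.18 (0.000655), oligodendrocyte markers at -0.17 (0.0141), GABAergic markers at -0.29 (0.0346), synaptic vesicle genes at -0.08 (0.0478) and pan-neuronal markers at -0.19 (0.0497). Pan-neuronal markers reached a median of 3.26% of their Dopa neuron Control level in SCZ and 4.16% in Control libraries. For the neuronal lists, neuronal RNA carried into these sorts was therefore not separated from a change in glia. In all lists 0 genes passed over all genes. fry called 0 lists. The mitochondrial percent of counts was 0.661 ± 0.515 in SCZ and 0.423 ± 0.355 in Control libraries (permutation p 0.0653, 0.392 adjusted over 6 measures).

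Comparing BP with Control in the Non neuron sorts asks the same for bipolar disorder. Among activity-induced genes, ARC stood at 1.25 ± 1.23 CPM in 8 BP libraries against 6.63 ± 10.9 in 26 Control libraries, -2.42 in 7 of 8, and EGR1 changed by -1.45. Of the lists 7 passed with the preset correlation, and adjusted p = 0.783 with an estimated correlation for each. The list of immediate early genes had 0 of 12 positive at a median of -0.76, adjusted p 0.000607. Heat shock genes had a median of -0.91, adjusted p 0.044, with HSP90AA1 at -1.04. GABAergic markers had 7 of 8 positive at a median of 0.82, adjusted p 0.0185, with GAD2 at 1.33 in 4 of 8. Without libraries that carried markers of the other sort the GABAergic list had adjusted p 0.163, and pan-neuronal markers reached a median of 6.25% of their Dopa neuron Control level in BP and 4.16% in Control libraries. GABA receptor genes had 12 of 13 positive at a median of 0.47, adjusted p 0.00626, and voltage-gated channel genes a median of 0.25, adjusted p 0.0185. Dopamine neuron markers had a median of -0.53, adjusted p 0.00627, and mitochondrially encoded genes -0.51, adjusted p 0.0375. In these 7 lists 0 genes passed over the list alone. fry called 0 lists.

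edgeR called 0 of 24755 genes in BP and gave 713 with an unadjusted p under 0.05, and limma-voom and DESeq2 called 0. At adjusted p 1.00 the lowest p values were those of IGSF3 at 1.66 in 4 of 8, RIMS3 at 1.30 ± 0.359 in 8 of 8, SPHKAP at 1.73 in 5 of 8 and KIT at 1.31 in 6 of 8. UPF3B, a factor of nonsense-mediated decay, stood at 83.5 ± 36.2 against 144 ± 59.4 CPM, -0.82 in 7 of 8.

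Whether a disorder changed the 2 sorts differently was tested as an interaction over all 6 groups. For BP the receptor tyrosine kinase gene KIT (ENSG00000157404.15, chromosome 4, 54657918 to 54740715) stood at 24.9 ± 36.1 CPM in the Dopa neuron BP libraries against 126 ± 129 in Control, lower in 8 of 9, while it leaned higher in the Non neuron sorts. Its interaction was -3.63 ± 0.728, adjusted p 0.0225. The kainate receptor gene GRIK1 stood at 170 ± 234 against 608 ± 559 CPM, with an interaction of -2.89 ± 0.628, adjusted p 0.0414. RGPD4, one of several near-identical copies, had -4.36 ± 0.921, adjusted p 0.0307. Each was lower in 8 of 9 BP libraries. edgeR called 11 of 27328 genes, all lower, and 2060 had an unadjusted p under 0.05. DESeq2 called 28, including 9 of the 11, and limma-voom called 0, with adjusted p 0.268 for KIT and GRIK1 and 0.331 for RGPD4. The interaction was not run with a marker index as a covariate or without libraries carrying markers of the other sort. A different makeup of the sorts in BP was therefore not tested for these genes.

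Not past the threshold in edgeR for BP came TMEM215 at -4.20, adjusted p 0.0827, and OTX2, SPHKAP, IGSF3 and NELL1 at -3.41, -3.29, -2.66 and -2.59, each at adjusted p 0.0953. DESeq2 called these 5, at adjusted p 0.0371 for TMEM215, 0.029 for OTX2 and IGSF3, 0.0282 for SPHKAP and 0.0337 for NELL1. With no filter on low counts edgeR also called them, at 0.0373 for TMEM215, 0.0391 for SPHKAP, 0.039 for IGSF3 and 0.0415 for OTX2 and NELL1. For SCZ edgeR called 0 of 27328 genes, with 1301 at an unadjusted p under 0.05, limma-voom called 1 and DESeq2 0. CARTPT at 3.91, ASB4 at -3.15 and ARHGAP11A at -1.68 had adjusted p 0.72, and SLC6A3 at -3.27 and CLTCL1 at -1.19 had 0.73. For the marker indices the BP interaction was 1.502 for dopamine neurons (permutation p 0.0154) and -0.71 for GABAergic neurons (permutation p 0.0161), both 0.0968 after adjustment over 12 lists. The SCZ interaction was -0.93 (permutation p 0.0814) and 0.54 (permutation p 0.0466), both 0.488 adjusted.

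Testing neighbouring genes together asks whether whole chromosomal domains moved. In the Dopa neuron sorts of SCZ, the imprinted region on chromosome 14 from 100000001 to 101000000, with MEG3, MEG8 and small nucleolar RNAs of the SNORD113 and SNORD114 families, had 5 of 68 genes positive at a median of -0.57, adjusted p 1.82e-06. Adjusted p = 0.965 with an estimated correlation for this and the other bins called in SCZ. The next bin had 45 genes at a median of -0.46, adjusted p 0.000638. Of 1651 bins of 1 Mb, 13 were lower and 14 higher. Among the higher were the histone cluster on chromosome 6 from 26000001 (32 genes, 0.53), the NR2F2 bin on chromosome 15 from 96000001 (9 genes, 0.81) and the OTX2 bin on chromosome 14 from 56000001 (8 genes, 0.62). In BP 78 bins were lower and 54 higher, with 0 past an estimated correlation (adjusted p = 0.796). Bins of 0.5 Mb in BP gave 71 lower and 28 higher and bins of 2 Mb 66 lower and 74 higher, so the balance of directions changed with bin size. The chromosome 14 bin from 101000001 had 41 of 45 genes positive at a median of 0.49, adjusted p 1.19e-05, whereas the NR2F2 bin had 0 of 9 positive at a median of -1.41 and the OTX2 bin a median of -1.81.

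In the Non neuron sorts the SNORD115 bin on chromosome 15 from 25000001, with 47 genes, had a median of -0.72 in SCZ, adjusted p 0.000239, among 2 lower and 3 higher of 1684 bins. Adjusted p = 0.969 with an estimated correlation. The same bin was higher in BP at a median of 0.08 with 31 of 47 positive, adjusted p 4.91e-06, among 0 lower and 5 higher. Adjusted p = 1.00 with an estimated correlation. The SNORD copies are near-identical, so these bins count few independent measurements. SNHG14, which spans part of the SNORD115 bin, stood at 5217 CPM in Dopa neuron and 906.5 CPM in Non neuron Control libraries. Neuronal RNA carried into the Non neuron sorts was therefore not excluded for that bin. No bin passed with an estimated correlation in any of the 4 comparisons, where the lowest adjusted p was 0.965, 0.796, 0.67 and 1.00 for SCZ and BP in the Dopa neuron sorts and SCZ and BP in the Non neuron sorts. Changes of adjacent genes correlated at Spearman 0.224, 0.292, 0.135 and 0.12 in that order. The permutation p was 0.001, the smallest that 1000 shuffles of gene order can give. Over coding genes that do not overlap the correlations were 0.14, 0.214, 0.116 and 0.119.

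The changes of SCZ and BP against the same Control libraries were compared across genes in the Dopa neuron sorts. Their Pearson correlation was -0.45 over 23779 genes, where unchanged groups that share a Control group gave a mean of 0.26 over 500 simulations. The covariance was -0.0762, against 0.0317 in the simulations. With the Control libraries divided between the 2 disorders, so that they shared none, the mean correlation over 100 divisions was -0.50.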

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

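All Dixon ratios here were computed on groups of 8 or 9 libraries, and the named genes among them were chosen after their comparisons were seen. A ratio is the gap between the highest or lowest library and its nearest neighbour, divided by the range of the group. Chance puts about 1 in 20 groups beyond the critical value. Among 54 groups of marker indices and library measures 10 were beyond it, and among 72 groups of named genes 12 were, with the highest library apart in 7 and the lowest in 5.

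In the Dopa neuron SCZ libraries microglial markers stood apart in 1 high library (0.652). Macrophage F13A1 (0.599) and the lipid transfer gene PLTP (0.621) stood apart high in the same group. T lymphocyte markers had a ratio of 0.719, the mitochondrial percent 0.647 and the small RNA percent 0.596. Among other genes of this group NR1D1 had 0.534, PLEKHG2 0.728, CCN3 0.635, KCTD6 0.585 and CARTPT 0.623.

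In the Dopa neuron BP libraries the GABAergic index had a ratio of 0.550 with 1 low library, T lymphocyte markers 0.550 with 1 high library and the mitochondrial percent 0.693. The vesicular transporter gene SLC18A2 had 0.504. PLTP had 0.600, FGFR4 0.560, NR1D1 0.658 and PEX5L 0.517. In the Non neuron BP libraries serotonin neuron markers had 0.562, endothelial and mural markers 0.597 and the log2 total count 0.580.

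The effect of BP differed between the 2 sorts for 11 genes by the interaction test, each lower in the Dopa neuron sorts relative to the Non neuron sorts, with KIT, RGPD4 and GRIK1 among them. limma-voom called 0 and DESeq2 28, and 9 of 100 divisions of the libraries gave as many, so chance cannot be excluded.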

How the results depend on the processing

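The dopamine neuron index and log2 total count as covariates, the sets without mixed or microglia-rich libraries and the TPM table were chosen after results were seen, and the other alternatives were planned. No paired analysis was possible because donor numbers were unique to each library. All alternatives gave values.

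The comparison of sorts gave 25030 genes with no filter on low counts, where genes absent from most libraries entered, and all 24 named genes kept direction and call in all 7 alternatives. The median change of all genes was -0.02 with edgeR on counts and -0.14 with limma on TPM, where 4842 genes were higher and 6764 lower and 10852 of the 15178 calls were kept. With no filter SCZ against Control gave 154 genes in the Dopa neuron and 374 in the Non neuron sorts, BP against Control 15 in the Non neuron sorts, SCZ against BP 2756, and the interactions 229 for SCZ and 49 for BP. The cause was not tested.

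SCZ against BP in the Dopa neuron sorts gave 0 genes with 2 surrogate variables, 0 with the dopamine neuron index as a covariate and 0 with limma on the TPM table, where both table and test changed. The median size of the 887 called changes went from 1.47 to 0.68, 0.53 and 0.84 there. With log2 total count as a covariate it gave 154 genes, at a median of 1.34, without libraries carrying markers of the other sort 176, without the microglia-rich SCZ library 554 and with only the 2 groups 1338. limma-voom gave 2175 and DESeq2 2097. Of the 24 named genes HHLA1 turned direction in the TPM table, at 0.034, and none was past adjustment there.

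Other gene counts moved with the tool. DESeq2 gave 6 genes for SCZ and 124 for BP against Control in the Dopa neuron sorts, 11 for SCZ in the Non neuron sorts and 28 for the BP interaction. limma-voom gave 6 for BP in the Dopa neuron sorts, 1 for the SCZ interaction and 0 for the BP interaction. Without libraries carrying markers of the other sort SCZ against Control gave 1 gene in the Dopa neuron sorts. Without the microglia-rich library the change of F13A1 was -0.23.

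Lists of genes held in none of the 4 case-control comparisons with an estimated correlation (0, 0, 0 and 0 lists) or with fry (0, 0, 0 and 0). Members of a list that vary together across libraries widen the spread of its mean, which the preset correlation of 0.01 understates. Without libraries carrying markers of the other sort 14 lists passed for SCZ and 2 for BP in the Dopa neuron sorts and 11 for BP in the Non neuron sorts. With the dopamine neuron index 1 list passed for BP. That index is the mean of the dopamine neuron list and shares 5 members with dopamine synthesis and handling, so the loss of both lists is built into the fit and decides nothing. They turned direction in BP (adjusted p 0.434 and 0.776) and in SCZ against BP (0.752 and 0.787). The index also turned mitochondrially encoded genes (0.259), proteasome (0.341) and protocadherins (0.899) in SCZ against BP.

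Chromosomal bins also passed in none of the 4 comparisons with an estimated correlation (0, 0, 0 and 0). SCZ in the Dopa neuron sorts had 16 bins of 0.5 Mb, 13 of 2 Mb and, of 1 Mb with the dopamine neuron index, 8. BP had 70 with that index. SCZ in the Non neuron sorts had 22 bins of 0.5 Mb.

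The remaining 61 values that answer a comparison stayed within 1.5 times the reported count. Among single genes, lists and indices 718 kept direction and call, 168 kept direction and lost the call, 33 gained a call and 9 turned direction.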

Other observations

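The tests of glial RNA for SCZ against BP, of dilution by glia and of library size for the dopamine markers, both tests of the chromosomal bins, the comparison of the Control slopes with other divisions of the libraries and the value that decided on library size for SCZ against BP were chosen after the results were seen.

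Dopamine transcripts varied widely among the Dopa neuron sorts of Control donors. SLC6A3 stood at 48.3 ± 72.5 CPM and TH at 49.9 ± 53.1 CPM over 24 libraries, so that the SD was as large as the mean, while SNAP25 stood at 303 ± 115 CPM and GAD2 at 150 ± 90.9 CPM. Transcripts of GABAergic neurons were therefore abundant beside those of dopamine neurons under the NeuN and Nurr1 gate. Across these 24 libraries the dopamine neuron index rose with the pan-neuronal index (Pearson 0.543, permutation p 0.00644, and Spearman 0.430, permutation p 0.0372). Pearson was 0.364 without the 2 libraries farthest from the median of the dopamine neuron index, here the 2 highest. Such libraries are called the 2 farthest from here on. The dopamine neuron index was then set against the oligodendrocyte index. It fell with the oligodendrocyte index (Pearson -0.551, permutation p 0.00524, and Spearman -0.591, permutation p 0.00264), and Pearson was -0.589 without the 2 farthest. Both had an adjusted p of 0.0386 over 12 measures. With the GABAergic index Pearson was -0.0899, permutation p 0.677, adjusted 0.885, and Spearman -0.215, permutation p 0.310, and without the 2 farthest Pearson was -0.144. The fall with the oligodendrocyte index was not seen in the 8 SCZ and 9 BP libraries, where Pearson was 0.520 (permutation p 0.189, adjusted 0.481, Spearman 0.476, permutation p 0.245, -0.0623 without the 2 farthest) and 0.127 (permutation p 0.743, adjusted 0.994, Spearman 0.133, permutation p 0.745, 0.289 without the 2 farthest). With the GABAergic index it was -0.768 in SCZ (permutation p 0.0310, adjusted 0.371, Spearman -0.738, permutation p 0.0458, -0.515 without the 2 farthest) and -0.302 in BP (permutation p 0.438, adjusted 0.994, Spearman -0.283, permutation p 0.465, -0.207 without the 2 farthest). With the pan-neuronal index Pearson was -0.304 in SCZ (permutation p 0.454, adjusted 0.681, Spearman -0.310, permutation p 0.462, 0.0974 without the 2 farthest). In BP it was 0.841 (permutation p 0.00398, adjusted 0.0478, Spearman 0.817, permutation p 0.0103, 0.590 without the 2 farthest).

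Markers of the other sort were present at low levels. Oligodendrocyte markers in the Dopa neuron sorts reached medians of 2.63% of the Non neuron Control level in Control, 2.14% in SCZ and 1.83% in BP libraries, and they exceeded 10% in 4 Control, 1 BP and 0 SCZ libraries. Pan-neuronal markers in the Non neuron sorts reached 4.16%, 3.26% and 6.25% of the Dopa neuron Control level, and they exceeded 10% in 4 Control, 2 SCZ and 1 BP libraries.

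The genes that differ between SCZ and BP in the Dopa neuron sorts went with the dopamine neuron index: of 869 called genes that are not markers 98.6% had the sign given by slopes on the dopamine neuron index fitted in Control libraries alone, against 80.0% of all such genes, and the slopes gave a median of 64.0% of the change (quartiles 47.4% to 78.1%). With a glial index as a covariate 94.6% of the calls stayed at a median change of 1.41, which argues against glial RNA as the whole cause. Without libraries that carried markers of the other sort 174 of the 887 calls stayed, and all 24 named genes kept direction and call. That set held fewer libraries, and the sizes of the 887 changes were not summarised in it, so the lost calls alone do not decide. With log2 total count 17.4% stayed, which met the bound set beforehand for library size as the cause, and 93.9% had the sign of Control slopes on log2 total, so the sign alone does not separate the 2 explanations. That bound counts calls and not changes: the median change went from 1.47 to 1.34 (SE 0.395 to 0.392) with 887 of 887 in the same direction, calls lay close to the threshold (ATP8B3 moved from adjusted p 0.0233 to 0.0335 and stayed), and Control slopes on log2 total gave 9.64% of the changes (quartiles 6.04% to 12.9%), which argues against library size as the whole cause. With the dopamine neuron index the calls ended because the changes shrank, from 1.47 to 0.535 (quartiles 0.305 to 0.958) at an SE of 0.371. The index differed by -2.47 between SCZ and BP, so as a covariate it takes up part of any difference between them. A different share of dopamine neurons among the sorted nuclei may explain most of the difference. The index is a mean of transcripts, so it does not separate this from fewer dopamine transcripts per neuron, which was not tested. The origin in tissue sampling, sorting or the disorders stays open.

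For the lower dopamine markers in the SCZ libraries, glia in the sort would lower dopamine and GABAergic markers alike, but the GABAergic minus dopamine index was 2.37 ± 0.857 in SCZ and 0.865 ± 1.43 in Control libraries (exact p 0.0091), which argues against dilution as the whole cause. Library size was not decided by the correlation of the dopamine neuron index with log2 total. Pearson was 0.430 over 24 Control libraries (permutation p 0.0316, adjusted 0.0947 over 12 measures, Spearman 0.155, permutation p 0.470) and 0.0646 without the 2 farthest. Those 2 were picked by the index itself, which narrows its range and can lower a correlation, so the drop decides nothing. In the 8 SCZ libraries Pearson was 0.588 (permutation p 0.136, adjusted 0.481, Spearman 0.429, permutation p 0.30) and 0.208 without the 2 farthest, while log2 total differed from Control by -0.11 (exact p 0.686). A smaller share of dopamine neurons stays open: Control slopes correlated at 0.487 with the SCZ changes over 23690 genes that are not markers, above the bound set beforehand, but the same Control libraries enter both. With separate Control libraries the mean was 0.415 (-0.0172 to 0.703 over 100 divisions), and 23 of 100 divisions of the Dopa neuron libraries gave as high a value (mean 0.266 for the others), so this correlation does not decide, and fewer dopamine transcripts per neuron in SCZ was not tested.

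The 27 bins called in the SCZ Dopa neuron sorts, among them the imprinted region of MEG3, were also fitted with the dopamine neuron index. With the dopamine neuron index as a covariate 2 stayed called, and the median change of the 27 went from 0.489 (quartiles 0.356 to 0.599) to 0.201 (quartiles 0.0988 to 0.269), with 25 in the same direction. The index differed by -1.20 between SCZ and Control, so as a covariate it takes up part of any difference between them. Slopes in the Control libraries alone were not summarised for the bins. The smaller changes therefore do not decide whether the bins go with the share of dopamine neurons. With a correlation estimated from the libraries 0 passed, so genes that vary together may account for the calls by a preset correlation. No biological explanation was tested for the bins.

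Other divisions of the libraries into groups of the same sizes, 100 for each result with the real one included, were compared with the real values. Between the 2 sorts 1 was as large as 15178 genes, the highest other being 3, so chance can be excluded. For SCZ against BP 3 were as large as 887, a share under the bound of 0.05 set beforehand. That share was not adjusted over the results tested, and the highest other gave 5662, several times the real count. Chance is therefore less likely here but not excluded. The value of 5662 points to a structure of the libraries, whose cause was not tested. For the BP interaction 9 were as large as 11, the highest other being 243, and chance cannot be excluded. Where edgeR called 0 genes any division gives as many, so the count of 100 decides nothing. The highest other there was 232 for SCZ and 837 for BP in the Dopa neuron sorts, 90 and 911 in the Non neuron sorts and 185 for the SCZ interaction.

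Chance cannot be excluded for the lists, bins or adjacent genes in the case-control comparisons. In the order SCZ and BP in the Dopa neuron sorts, then SCZ and BP in the Non neuron sorts, the lists called were 5, 5, 12 and 7. Divisions as large numbered 76, 79, 24 and 58, with 16, 20, 20 and 18 as the highest other. The bins called were 27, 132, 5 and 5, and divisions as large numbered 50, 10, 73 and 68, with 216, 192, 172 and 194 as the highest other. For the correlation of adjacent genes, at 0.224, 0.292, 0.135 and 0.120, they numbered 28, 7, 63 and 72, with 0.353, 0.320, 0.278 and 0.323 as the highest other.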
